A study of Mus musculus with 24 samples.

How the data were processed

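Total RNA of the right hippocampus was labelled with biotin and hybridised to exon arrays of the Affymetrix Mouse Exon 1.0 ST type, per the labels' protocols, 1 array for each of 24 mice in 4 groups of 6. The deposited values are log2 expression values, 1 per row and array, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, normalizes probes by quantiles and summarises them per row by median polish. Versions, the summary level and the annotation used are not given in the sources used here. The table held 23238 rows with 0 missing values. Array medians ran from 5.05 to 5.43 and upper quartiles from 7.05 to 7.72, so the summarised values were not on exactly equal distributions, and quantile normalization and centring were tried as alternatives. No array pair held identical values. Background per probe was not part of the table, so no row was called undetected, and low values carry little signal.

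Rows were named from the platform annotation that accompanies the table. Of the rows 14939 carry 1 gene symbol, 989 carry several and 7310 are unnamed here, and only rows with 1 symbol were named in the text. Of the 14939, 14884 were found by Entrez identifier in the RefSeq gene table of GRCm38.p6, and 0 of these had another current symbol. A total of 131 genes had more than 1 such row, and gene lists used the row with the highest mean over all arrays. Among these 131 genes, 45 had a row past the threshold in the comparison of EPO in sham, 16 had all rows past it, and 0 had rows past it in opposite directions. List genes were matched by their exact symbol only, since matching older symbols gave wrong genes, which departs from the plan. No genome coordinates are given, since the build behind the array annotation is not given.

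Groups follow the mouse status and treatment in the sample characteristics. The titles can be read in another way that exchanges injured none and sham EPO, and this was planned as an alternative. No measurement used here settles which reading holds, so groups are named as labelled. Replicates were numbered in accession order and do not pair mice. The titles also carry a letter code with 7 values, whose meaning the labels do not give. It was used as a fixed block, as a random block and by keeping the 11 arrays of code 3D, which holds 2 sham none, 2 sham EPO, 4 injured none and 3 injured EPO arrays.

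Each row was fitted in limma 3.58.1 under R 4.3.3 with 1 mean per group over all 24 arrays, 20 residual degrees of freedom (23.3 with the empirical Bayes prior), and 8 contrasts. P values were adjusted by the Benjamini-Hochberg method over all rows, with a threshold of 0.05, with no filter on level. The contrasts were injury without and with EPO, EPO in sham and in injured mice, their interaction, both averaged effects, and injured EPO against sham none. The 31 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, with camera at an estimated correlation and with fry beside it. A list count is the number of members past the threshold over all rows, and beside it is the number when p values were adjusted over the list alone. The reversal slope used every division of the injured none arrays into equal sets, with an exact permutation over 924 assignments.

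The text names, per contrast, the 10 largest rises and the 10 largest falls among rows past the threshold, up to 4 members per list with the largest difference, the 5 smallest p where fewer than 5 rows pass, and a fixed set of genes (Epor, Epo, Cish, Socs3, Bcl2l1, Bdnf, Gfap, Aif1, Ccl2, Hmox1, Vegfa, Alas2 and Hbb-b1, with 1 more that is not reported here). Not every gene of the rule is written out. Hbb-b1, Xist and Ddx3y have no row that carries the symbol alone. Other genes are said to be named after their values were seen.

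The fit was tested on 5 simulated data sets of 23238 rows with 200 changed rows. In the contrast of EPO in sham 52.8% of rows changed 1.5-fold and 84.4% of rows changed 2-fold were recovered, with 4.4 false calls on average, and for the interaction 24.8% and 62.6% with 4.8 false calls. The unchanged contrast of injury without EPO gave 0 calls. The simulated rows were independent and normal, with the same spread in every group and far fewer changed rows than were called here. The mean residual variance of the real groups ran from 0.0787 to 0.132, so these rates need not hold for the real arrays. Groups, contrasts, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Alternatives covered the normalization between arrays, dim rows, rows with 1 symbol, the variance model, array weights, the title code, the arrays in the fit, the reading of the titles, each replicate left out, and the threshold. Added after seeing the data were the level of Eif2s3y as a covariate, leaving out 2 arrays in doubt, and weights for unequal group variances.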

Results

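Gene expression was measured in the right hippocampus of 24 BALB-c mouse pups aged 10 days, with 1 Affymetrix Mouse Exon 1.0 ST array per pup. The right side was the side of the carotid artery ligation. The labels give 4 groups of 6 mice: sham-injured without erythropoietin (titles starting Sham_N), sham-injured with high-dose recombinant erythropoietin (Sham_Y), brain-injured without it (Epo_N) and brain-injured with it (Epo_Y). Erythropoietin (EPO) is the hormone that drives red cell formation. The series title names its use in a unilateral brain injury of the newborn mouse, so the comparisons ask what injury changed, what EPO changed, and whether EPO altered the response to injury. The dose and timing of EPO and the day of the injury are not given in the sources used here. The table held 23238 rows of log2 values on every array, of which 14939 carried 1 gene symbol. Array medians ran from 5.05 to 5.43 and the correlation between any 2 arrays from 0.952 to 0.993. The number of arrays, 6 per group, limits the precision. The median standard error (SE) of a difference between 2 groups was 0.14 on the log2 scale. With 1 array per mouse, the p values rest on the spread between arrays. That spread holds differences between mice, dissections and arrays together.

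The groups follow the mouse status and treatment that each sample's characteristics state. The titles allow another reading, in which the first word is the treatment and the letter that follows it the injury. That reading exchanges injured without EPO and sham with EPO and leaves the other 2 groups in place. Each direction below is therefore that of the groups as labelled. With the titles read the other way, the comparison of sham EPO with sham none becomes that of injury without EPO, and the comparison of injured EPO with sham EPO becomes that of EPO in injured mice.

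The arrays labelled sham EPO differed from those labelled sham none more widely than any other pair of groups tested here, with genes of inflammation and of reactive astrocytes higher and neuronal genes lower. Ccl3, a chemokine that attracts monocytes and macrophages (row 6790294), rose by 6.95 ± 0.87 (log2 difference ± SE, n = 6 per group), from 3.65 ± 0.15 (SD) to 10.61 ± 0.28. Lcn2, the iron-siderophore binding lipocalin of reactive astrocytes (row 6885873), rose by 6.05 ± 0.42, from 3.61 ± 0.22 (SD) to 9.66 ± 0.78, a 66.2-fold difference. The imprinted noncoding RNA H19 (row 6972314) rose by 5.36 ± 0.50. Among the largest falls, Neurod6, a transcription factor of pyramidal neurons (row 6953866), fell by 2.31 ± 0.46. Fibcd1, a marker of CA1 pyramidal neurons (row 6885836), fell by 2.12 ± 0.20. Limma called 4445 of 23238 rows at an adjusted p of 0.05, 2679 higher and 1766 lower in the labelled sham EPO arrays. Of these, 657 rose and 176 fell by at least 2-fold.

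The 10 largest rises also held Ccl9, another chemokine (5.14 ± 0.58), Timp1, an inhibitor of matrix metalloproteinases (4.65 ± 0.42), and Hmox1, the heme-degrading enzyme heme oxygenase 1 (4.57 ± 0.42). C3ar1, the receptor of complement fragment C3a, rose by 4.56 ± 0.51, the crosslinking enzyme gene Tgm1 by 4.43 ± 0.40, the lipid droplet gene Plin2 by 4.18 ± 0.42 and the chemokine gene Ccl12 by 3.97 ± 0.43. All 6 labelled sham EPO arrays lay above every sham none array for each of these 10 genes. The 10 largest falls also held Itgbl1 (-2.27 ± 0.30), Ak4, a mitochondrial adenylate kinase (-1.97 ± 0.35), Thsd4 (-1.97 ± 0.22), 9330120H11Rik (-1.88 ± 0.25), Pkp2, a desmosome protein (-1.83 ± 0.23), and the heparan sulfate enzyme gene Ndst4 (-1.83 ± 0.26). Npy2r, a neuropeptide Y receptor (-1.75 ± 0.27), and Hpca, the calcium sensor hippocalcin (-1.73 ± 0.17), completed them. Ak4 lay below every sham none array on 5 of the 6 arrays, and the others among these 10 genes on all 6. Adjusted p over these 20 genes ran from 8.95e-10 for Lcn2 to 0.000587 for Neurod6.

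**Figure D1:**
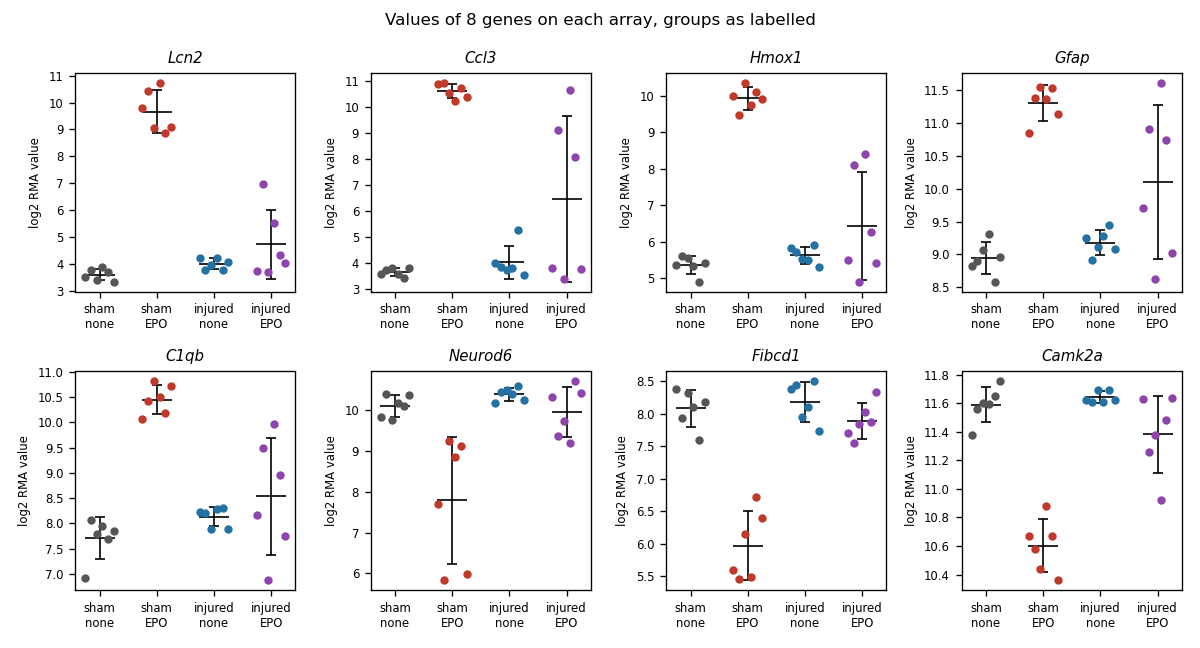
Log2 RMA values of 8 genes (vertical axis) on each of the 24 arrays, by group as labelled (horizontal axis); each point is 1 array, the horizontal bar the mean and the whiskers the SD of 6 arrays. For Lcn2, Ccl3, Hmox1, Gfap and C1qb the 6 labelled sham EPO arrays lie above every sham none array, for Neurod6, Fibcd1 and Camk2a below, and for Lcn2, Ccl3, Hmox1, Gfap and C1qb the labelled injured EPO arrays have the largest SD of the 4 groups.

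Of the 31 gene lists, those of glial activation and inflammation held the largest share of rises in the labelled sham EPO arrays. Reactive astrocyte genes rose in 14 of 17 measured members and fell in none (15 adjusted over the list alone), with a median log2 difference of 2.37. Examples were Osmr, the oncostatin M receptor (3.30 ± 0.37), Emp1 (3.14 ± 0.21) and Gfap, the astrocyte filament protein (2.37 ± 0.33). Genes of phagocytic and lysosomal microglia rose in 12 of 14 (13 adjusted over the list alone), among them the scavenger receptor gene Msr1 (3.61 ± 0.31), Gpnmb (3.22 ± 0.28) and the lysosomal marker Cd68 (3.13 ± 0.37). Cytokines and chemokines rose in 17 of 19 (17 adjusted over the list alone), with Cxcl16 at 2.61 ± 0.24, Ccl4 at 2.49 ± 0.32 and Ccl2 at 2.18 ± 0.14. Complement genes rose in 8 of 9 (8 adjusted over the list alone), including the C1q chains C1qa (2.30 ± 0.22), C1qb (2.74 ± 0.34) and C1qc (2.27 ± 0.25). Interferon response and MHC class I genes rose in 11 of 11 (11 adjusted over the list alone), with Gbp2 at 2.39 ± 0.29, Ifit1 at 2.38 ± 0.54 and Irf7 at 2.05 ± 0.28. Perivascular macrophage genes rose in 8 of 8 (8 adjusted over the list alone), among them F13a1 (2.24 ± 0.23) and Lyve1 (1.98 ± 0.23). The p53 and apoptosis list rose in 10 of 17 (10 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.85 ± 0.26 and Casp8 at 1.71 ± 0.19. Extracellular matrix and fibroblast genes rose in 14 of 18 (17 adjusted over the list alone), with Fn1 at 1.73 ± 0.26 and Col4a1 at 1.17 ± 0.12.

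Among the identity markers of microglia and astrocytes some rose and others fell. Of 14 measured microglia identity genes, 5 rose and 4 fell in the labelled sham EPO arrays (7 and 4 adjusted over the list alone), and camera gave no call (adjusted p = 0.233). Their median was 0.15, and -0.03 with each array centred on its median. Irf8 (1.60 ± 0.14) and the integrin gene Itgam (1.56 ± 0.20) rose. The 4 that fell, named after their values were seen, were the purinergic receptor gene P2ry12 (-0.53 ± 0.11), Tmem119 (-0.60 ± 0.17), Siglech (-0.72 ± 0.12) and Selplg (-0.91 ± 0.17). Astrocyte identity genes rose in 3 of 13 and fell in 1 (3 and 1 adjusted over the list alone), with the water channel Aqp4 at 0.80 ± 0.15 and a camera adjusted p of 0.326. With each array centred on its median 3 rose and 3 fell. Endothelial and pericyte genes rose in 15 of 19 (16 adjusted over the list alone), with the junction protein Cdh5 at 1.90 ± 0.19 and Pecam1 at 1.62 ± 0.21. With an estimated correlation the adjusted p of that list was 0.0564. Infiltrating leukocyte genes rose in 7 of 18 (7 adjusted over the list alone), among them the leukocyte common antigen Ptprc (1.66 ± 0.16) and S100a8 (1.13 ± 0.32), which did not pass with the title code as a block or with only the sham groups in the fit. The adjusted p of the leukocyte list with an estimated correlation was 0.384, and its median of 0.07 became -0.11 with each array centred on its median.

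Neuronal genes fell in the labelled sham EPO arrays. Of 21 measured neuronal and synaptic genes 18 fell and none rose (20 fell adjusted over the list alone), with a median of -0.71. They included the glutamate receptor subunits Grin2a (-1.42 ± 0.18) and Gria1 (-1.07 ± 0.12), the neurofilament Nefl (-1.07 ± 0.10) and the kinase gene Camk2a (-0.99 ± 0.11). Hippocampal pyramidal and granule neuron genes fell in 11 of 19 (12 adjusted over the list alone), and Itpka, an inositol phosphate kinase, fell by 1.40 ± 0.17. Of 15 measured interneuron genes 1 passed, the neuropeptide gene Cck (-0.79 ± 0.10; 1 adjusted over the list alone), and camera gave no call (adjusted p = 0.0777). With each array centred on its median 7 of the 15 fell. Cholesterol biosynthesis genes fell in 9 of 15 (12 adjusted over the list alone), among them Sqle (-0.92 ± 0.15), Hmgcs1 (-0.84 ± 0.09) and Cyp51 (-0.81 ± 0.14).

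**Figure D2:**
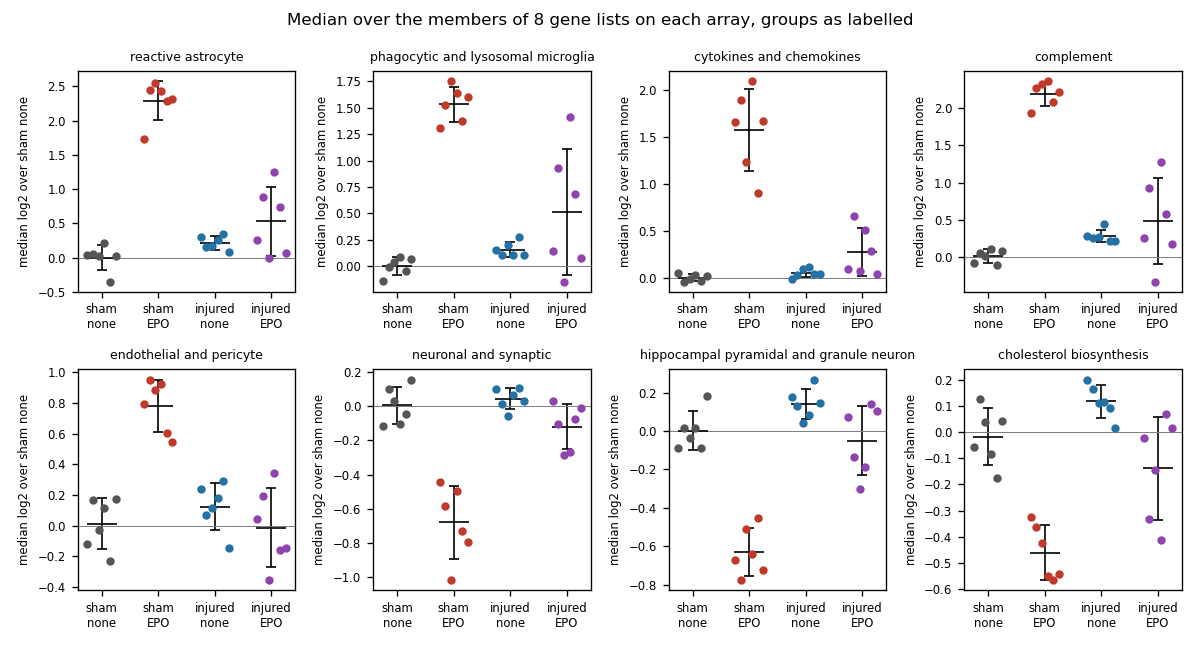
Median over the measured members of 8 gene lists, as the log2 difference from the mean of the sham none arrays (vertical axis), on each of the 24 arrays by group as labelled (horizontal axis); each point is 1 array, the horizontal bar the mean and the whiskers the SD of 6 arrays. The 6 labelled sham EPO arrays stand apart from sham none in every panel shown, and the labelled injured none arrays lie near sham none.

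The list of the EPO receptor and STAT5 pathway, through which EPO signals, rose in 11 of 18 members and fell in 1 (13 and 1 adjusted over the list alone). Socs3, a feedback inhibitor of cytokine receptors, rose by 2.27 ± 0.18, the shared cytokine receptor chain Csf2rb by 1.94 ± 0.24 and Stat3 by 1.65 ± 0.22. These genes are not particular to EPO, and Stat3 is also on the reactive astrocyte list, so the count does not by itself show EPO signalling. The STAT5 target Cish rose by 0.38 ± 0.12 (adjusted p = 0.0318) and did not pass after either rescaling of the arrays or with the title code as a block, nor without any 1 of sham none replicates 1, 2, 5 and 6 or sham EPO replicates 1 to 4. Socs2, another STAT5 target and the member that fell, named after its value was seen, fell by 0.81 ± 0.21 and did not pass with the title code as a block. Epor, the EPO receptor gene, measured 5.05 ± 0.16 (SD) in sham none, 4.97 ± 0.14 in sham EPO, 5.20 ± 0.24 in injured none and 5.20 ± 0.11 in injured EPO, as labelled. Epo measured 2.60 ± 0.11 in sham none and 2.71 ± 0.27 in sham EPO. The Y-linked gene Eif2s3y read 2.50 to 2.84 on the 13 arrays of its lower set. Epo lay at a similar level, so its values carry little signal. Vegfa (7.80 ± 0.14 and 7.63 ± 0.14), Bdnf (6.01 ± 0.21 and 5.70 ± 0.25), Bcl2l1 (6.45 ± 0.14 and 6.67 ± 0.09) and the erythroid heme enzyme Alas2 (6.21 ± 0.62 and 6.85 ± 0.37) did not pass in this comparison either, nor did Epor or Epo. Of 10 measured erythroid genes none rose and 2 fell (2 adjusted over the list alone), 1 of them the transferrin receptor Tfrc (-0.74 ± 0.21), which did not pass with the title code as a block. Camera gave no call (adjusted p = 0.526), and the median of the list was 0.05 while its mean was -0.04.

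Several lists were called by camera with its preset correlation and lost the call with an estimated one. Iron and heme handling rose in 10 of 15 and fell in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), with the iron carrier Trf at 1.31 ± 0.34 and the iron exporter Slc40a1, named after its value was seen, at -0.56 ± 0.17. The call of Slc40a1 was lost with the title code as a block and without any 1 of sham none replicate 6 or sham EPO replicates 2, 5 and 6. The oxidative stress (NRF2) list rose in 8 of 15 (9 adjusted over the list alone), with Gpx1 at 1.39 ± 0.20 and the metallothionein Mt2 at 1.31 ± 0.20, and its adjusted p with an estimated correlation was 0.113. Cell cycle genes rose in 13 of 19 (15 adjusted over the list alone), with Mcm6 at 1.27 ± 0.21 and Top2a at 1.01 ± 0.26, and an adjusted p of 0.183 with an estimated correlation. The heat shock and unfolded protein list rose in 5 of 16 and fell in 1 (7 and 1 adjusted over the list alone), with the stress transcription factor Atf3 at 3.73 ± 0.41 and Hsph1, which did not pass with the title code as a block, at -0.52 ± 0.13. The list's adjusted p with an estimated correlation was 0.391. Growth and neurotrophic factors rose in 5 of 17 (5 adjusted over the list alone), with Igfbp3 at 2.06 ± 0.18 and Angpt2 at 1.84 ± 0.21, and an adjusted p of 0.183 with an estimated correlation. With each array centred on its median 4 of them rose and 3 fell.

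Over the 31 lists camera called 16 up and 3 down in this comparison, and 12 of the 19 held with an estimated correlation. Each of these 12, the cholesterol, neuronal and p53 lists among them, had an adjusted p under 0.05 there. Fry called 22 lists. The direction and size of the share of rises depended on the scaling: rises were 60.3% of the called rows as deposited, 49.2% after another quantile normalization and 29.5% with each array centred on its median. Centring moved the median of all rows from 0.03 to -0.15. Reactive astrocyte genes then rose in 14 and fell in 1 of 17, p53 and apoptosis genes rose in 9 and fell in 1 of 17, endothelial and pericyte genes rose in 14 and fell in 1 of 19, and neuronal and synaptic genes fell in 21 of 21. No gene named as past the threshold in this comparison changed sign under either scaling. With the title letter code, whose meaning is not given, as a fixed block 3163 rows were called for EPO in sham, and 862 within the 11 arrays of code 3D.

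The labelled injured none arrays were close to those of sham none. Limma called 0 of 23238 rows, with 1803 rows at an unadjusted p under 0.05 where chance gives 1161.9, and the smallest adjusted p was 0.234. With the title code as a block or within code 3D the count was also 0. Gfap measured 9.18 ± 0.19 (SD) against 8.94 ± 0.24, Hmox1 5.63 ± 0.23 against 5.36 ± 0.25, Ccl2 4.16 ± 0.13 against 4.19 ± 0.16 and the microglial gene Aif1 5.48 ± 0.16 against 5.30 ± 0.21. Small differences were still seen in genes named after their values were seen. All 6 labelled injured none arrays lay above every sham none array for C1qa (8.03 ± 0.13 against 7.60 ± 0.19) and C3ar1 (4.98 ± 0.21 against 4.30 ± 0.28). For Irf8 and Itgam 0 of the 6 did. The 5 genes with the smallest p, none of which passed, were the odorant receptor gene Olfr1413 (-0.97 ± 0.19), Agmo (0.54 ± 0.12), Tmem86a (0.55 ± 0.12), the growth factor gene Bmp4 (0.77 ± 0.18) and 2810032G03Rik (0.45 ± 0.11). Camera called 3 lists up, microglia identity (median 0.20), iron and heme handling (0.21) and cell cycle (0.22), each at an adjusted p of 0.0486. All 3 had an adjusted p of 0.848 with an estimated correlation, and no list was called by fry. With each array centred on its median 1 row passed. With the titles read the other way this comparison takes the labelled sham EPO arrays and calls 4445 rows.

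Among mice given EPO, the labelled injured arrays had lower inflammatory and higher neuronal expression than the labelled sham arrays. Lcn2 fell by 4.93 ± 0.42, Ccl3 by 4.14 ± 0.87, H19 by 3.68 ± 0.50, Hmox1 by 3.49 ± 0.42 and the eotaxin gene Ccl11 by 3.27 ± 0.15. Saa3, an acute phase protein, fell by 3.18 ± 0.37 and Ccn1, a matrix protein, by 2.97 ± 0.32. Neurod6 rose by 2.16 ± 0.46, Itgbl1 by 2.10 ± 0.30, Fibcd1 by 1.92 ± 0.20, the nicotinic receptor subunit Chrna5 by 1.62 ± 0.31, the calcium channel gene Orai2 by 1.60 ± 0.24, the receptor gene Gpr63 by 1.55 ± 0.30 and the neuropeptide gene Grp by 1.52 ± 0.27. Limma called 3226 rows, 1407 higher and 1819 lower in the labelled injured EPO arrays. Neuronal and synaptic genes rose in 17 of 21 (19 adjusted over the list alone) and pyramidal and granule neuron genes in 9 of 19 (11 adjusted over the list alone). Reactive astrocyte genes fell in 14 of 17 (15 adjusted over the list alone), cytokines and chemokines in 15 of 19 (17), complement genes in 8 of 9 (8), perivascular macrophage genes in 8 of 8 (8), endothelial and pericyte genes in 15 of 19 (17) and matrix genes in 13 of 18 (15). These 8 lists were the ones that held with an estimated correlation, of 4 called up and 19 called down. The phagocytic microglia list, with 11 of 14 lower and 0 higher (12 and 1 adjusted over the list alone), had an adjusted p of 0.0715 with an estimated correlation.

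This comparison shares its 6 labelled sham EPO arrays with that of EPO in sham, with the opposite sign, so the pair is not independent. Fitted to the 12 arrays of its own groups alone, injury with EPO called 2019 rows, and within title code 3D it called 437. Rises were 43.6% of calls as deposited and 69.0% with each array centred on its median, which moved the median of all rows from -0.01 to 0.11. With the titles read the other way it becomes EPO in injured mice.

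EPO in the labelled injured mice gave no called row. Limma called 0 rows with 1892 at an unadjusted p under 0.05 and a smallest adjusted p of 0.539, and 0 also with the title code as a block. Gfap measured 10.10 ± 1.17 (SD) in the labelled injured EPO arrays against 9.18 ± 0.19 in injured none, Hmox1 6.44 ± 1.48 against 5.63 ± 0.23 and Socs3 5.84 ± 0.35 against 5.36 ± 0.31. The spread of the injured EPO arrays was wide: Gfap read 9.71, 10.92, 8.63, 11.62, 10.74 and 9.02 on replicates 1 to 6, which are numbered in no order, and the mean residual variance of this group was 0.132 against 0.0787 to 0.0911 in the others. Replicate 3 of this group had the lowest median (5.05), the lowest upper quartile (7.05) and the lowest array weight (0.237) of the 24 arrays. The 5 genes with the smallest p, which did not pass, were Olfr1413 (0.95 ± 0.19), Aifm3 (-0.48 ± 0.10), Retn (0.37 ± 0.09), Sh3bp1 (-0.42 ± 0.10) and Agmo (-0.49 ± 0.12). Camera called 10 lists up and 5 down with its preset correlation, among them cytokines and chemokines (median 0.39, 0 of 19 members past the threshold and 0 adjusted over the list alone) and cholesterol biosynthesis (median -0.29, 0 of 15, and 6 lower adjusted over the list alone). None held with an estimated correlation, where the smallest adjusted p was 0.171, and fry called 1 list, cholesterol biosynthesis (adjusted p = 0.0190).

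The response to EPO differed between labelled injured and sham mice in a direct test of the interaction, which takes the same values under both readings of the titles. The interaction is the EPO difference in injured mice minus that in sham mice. It was -5.33 ± 0.59 for Lcn2, -4.57 ± 0.70 for H19, -4.53 ± 1.24 for Ccl3, -3.76 ± 0.59 for Hmox1 and -3.28 ± 0.52 for Anxa1, an annexin of the anti-inflammatory response. It was 2.02 ± 0.43 for Itgbl1, 1.82 ± 0.28 for Fibcd1, 1.61 ± 0.37 for Cpne7 and 1.32 ± 0.24 for Hpca. Ccl3 did not pass with the title code as a block or without injured EPO replicate 6. Limma called 1696 rows, 360 above and 1336 below 0. Perivascular macrophage genes passed below 0 in 8 of 8 (8 adjusted over the list alone), complement genes in 8 of 9 (8), reactive astrocyte genes in 12 of 17 (16) and cytokines in 11 of 19 (14). Neuronal and synaptic genes passed above 0 in 10 of 21 (16 adjusted over the list alone) and pyramidal and granule neuron genes in 4 of 19 (6). These 6 lists held with an estimated correlation, of 3 called up and 18 called down. With the title code as a fixed block 902 rows were called and within code 3D 56. Values above 0 made up 21.2% of calls as deposited, 42.7% after another quantile normalization and 57.0% with each array centred on its median, which moved the median of all rows from -0.08 to 0.12.

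The averaged contrasts combine comparisons that were unlike, so an average does not describe a difference common to both. Injury called 0 rows without EPO and 3226 with it, EPO called 4445 in sham and 0 in injured mice, and the interaction called 1696. Lcn2, for example, measured 3.61 in sham none, 9.66 in sham EPO, 4.01 in injured none and 4.73 in injured EPO, as labelled. The contrast of injury averaged over EPO called 1557 rows, 1008 higher and 549 lower, with Neurod6 at 1.22 ± 0.32 (not past the threshold with the title code as a block), Lcn2 at -2.27 ± 0.29 and Ccl11 at -1.60 ± 0.10. Rises were 64.7% of these calls and 46.0% after another quantile normalization. This count was 3293 with array weights, 2511 without injured EPO replicate 3, 945 with the title code as a block and 13 within code 3D. The contrast of EPO averaged over injury called 3379 rows, 1586 higher and 1793 lower, with Ccl3 at 4.69 ± 0.62, Lcn2 at 3.38 ± 0.29 and Thsd4 at -1.39 ± 0.16. Rises were 46.9% of these calls and 26.4% with each array centred on its median, and the count was 2618 with the title code as a block and 732 within code 3D. With the titles read the other way the 2 averaged contrasts change places.

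Injured EPO against sham none, a comparison that is the same under both readings, called 0 rows with 1374 at an unadjusted p under 0.05 and a smallest adjusted p of 0.564. The 5 genes with the smallest p did not pass: Olfr1265 (-0.50 ± 0.10), Tmem176b (0.55 ± 0.12), C1qa (0.94 ± 0.22), Gem (0.88 ± 0.21) and Dhrs1 (0.71 ± 0.17). Leaving out injured EPO replicate 3 or replicate 6 gave 1 called row, and Tmem176b passed without replicate 3. Camera called 13 lists up and 3 down, phagocytic microglia (median 0.56) and reactive astrocyte (0.44) among those up, with 0 members past the threshold and 10 of each higher adjusted over the list alone. None held with an estimated correlation, where the smallest adjusted p was 0.206, and fry called none.

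Whether EPO reversed injury changes could not be decided with the groups as labelled. Injury without EPO called 0 rows, so there was little injury difference to reverse and a slope near 0 says nothing about reversal. Across rows, which are not independent replicates, the slope of the EPO difference in injured mice on the injury difference without EPO was -0.115 when the injured none arrays were divided so that the differences shared no array. An exact two-sided permutation of the EPO labels among the injured arrays gave p = 0.505 over 924 assignments. Without injured EPO replicate 3 the slope was 0.0310. With the injured none arrays shared, which alone pulls the slope below 0, it was -0.547. With the titles read the other way the slope without shared arrays was -0.642, with an exact permutation p of 0.00108. The overlap of calls between the injury comparisons could only be 0, since injury without EPO called 0 rows. Their log2 differences correlated across rows at a Pearson r of -0.0774. The EPO differences in sham and in injured mice, which share no array, correlated across rows at 0.310.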

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

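The tests of explanations and the splits of the arrays in this part were chosen after the results were seen, while the interaction was planned. The tests of Ttr and the choroid plexus were prompted by the low Ttr value itself, and only their bounds were set in advance.

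The labelled sham EPO arrays stood apart and the labelled injured none arrays did not. Over the 49 distinct members of the reactive astrocyte, phagocytic microglia and cytokine lists, the mean of the array medians relative to sham none was 0.13 ± 0.06 (SD, n = 6) in labelled injured none and 1.84 ± 0.19 in labelled sham EPO, with no overlap between these arrays. With the groups as labelled, an EPO response of equal size in both states is argued against by the interaction, which called 1696 of 23238 rows. Across the 4445 rows called for EPO in sham, the slope of the EPO difference in injured on that in sham mice was 0.175. It ran from 0.113 to 0.220 with each injured array left out. Choosing those rows by the sham difference itself pulls this slope down, by an amount that was not measured. A batch along the title code is argued against as the whole cause, since 3163 rows were called for EPO in sham with the code as a block and 862 within code 3D. An exchange of the labels injured none and sham EPO, which the titles allow, may explain the pattern. So may a response to EPO that was weaker in injured than in uninjured tissue, with an injury that left little trace. The interval after that injury is not given in the sources used here. These explanations cannot be told apart, since the values of 0.13 and 1.84 restate the pattern and both explanations need them.

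The labelled injured EPO arrays were spread out along the difference between sham EPO and sham none. With 0 for sham none and 1 for sham EPO, replicates 1 to 6 lay at 0.0658, 0.481, 0.0585, 0.581, 0.245 and 0.00121, against a range of 0.797 to 1.05 for labelled sham EPO and -0.0214 to 0.149 for sham none. Whole arrays exchanged with the sham EPO group are argued against, since the highest injured EPO array, at 0.581, lay below every labelled sham EPO array. A batch along the title code is argued against too, since injured EPO arrays of a shared code differed by up to 0.523 of a total range of 0.580. An unequal injury or an unequal response to EPO between mice may remain as an explanation and was not tested.

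Ttr, the transport protein that choroid plexus makes in large amounts, was low in sham none replicate 5, at 6.52 against 12.46 to 13.26 on the other 23 arrays. Of the 9 other measured choroid plexus genes 8 were lowest of all 24 arrays in this array, with a median difference of -1.60 from the other 5 sham none arrays; the exception was Otx2 (-1.05). Clic6 differed by -3.34, Sostdc1 by -3.63, Folr1 by -2.14 and Kl by -1.60. A failure of the Ttr row alone is argued against by these 8 genes, and less choroid plexus in this dissection is a candidate explanation that meets its prediction. No biological explanation was tested.

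Other splits of the same arrays, 100 for each contrast with the real one included, were drawn to count their called rows. For EPO in sham only 1 split, the real one, reached 4445 rows, and the highest other gave 1634. The real split also stood alone for injury with EPO (3226 against 2496) and injury averaged over EPO (1557 against 969). It did so too for EPO averaged over injury (3379 against 1). These values argue against chance only as far as 1 in 100, the finest share that 100 splits can show. The contrasts share the 6 labelled sham EPO arrays, so they are not separate results. For the interaction the real count was 1696 and the highest other 1. Its splits shuffled all 24 arrays over the 4 groups, which breaks up every group difference, so they cannot single out the interaction. For injury without EPO and EPO in injured, with 0 called rows, all 100 splits reached the real count, as any split must, which says nothing about chance, and the highest others gave 7 and 2. For injured EPO against sham none, also 0 and therefore reached by all 100 splits, another split called 3262 rows. Such a split points to a structure among these 12 arrays that the groups do not follow.

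The effect of EPO differed between labelled injured and sham mice in the test of the interaction, for 1696 rows. The 10 named genes highest above 0 were Itgbl1 (2.02), Fibcd1 (1.82), Npy2r (1.61), Cpne7 (1.61), Grp (1.53), Ndst4 (1.44), Pcdh20 (1.38), Nr4a2 (1.35), Hpca (1.32) and Mal2 (1.28). The 10 farthest below 0 were Lcn2 (-5.33), H19 (-4.57), Ccl3 (-4.53), Hmox1 (-3.76), Ccl9 (-3.69), C3ar1 (-3.50), Ccl11 (-3.35), Timp1 (-3.29), Anxa1 (-3.28) and Plin2 (-3.27). Of these 20 genes, Nr4a2 lost its call without sham none replicate 5 or injured EPO replicate 1, and Ccl3 without injured EPO replicate 6. With the title code as a block Npy2r, Grp, Pcdh20, Nr4a2, Ccl9 and Ccl3 did not pass.

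Single arrays also lay far from the other 5 of their group. Of 592 such tests of genes, list medians and array measures 30 passed Dixon's limit, where chance gives 29.6, so a single value alone carries little weight, apart from that of Ttr, which other choroid plexus genes accompany. The values are the gap to the nearest array as a share of the group's range. In sham none replicate 5 they were 0.956 for low Ttr, 0.673 for a low reactive astrocyte median, 0.634 for low Hmox1, 0.653 for low Plin2 and 0.633 for low Mcm6, and in sham none replicate 1 0.683 for low C1qb. Among labelled sham EPO arrays, replicate 1 had a low reactive astrocyte median (0.674) and high Epo (0.736), replicate 2 a high erythroid median (0.735), high Cd68 (0.645) and high Lyve1 (0.844), replicate 4 a high HIF target median (0.636) and replicate 6 a low astrocyte identity median (0.735). Among labelled injured none arrays, replicate 2 had high Ccl2 (0.705), low Stat3 (0.737) and low Olfr1413 (0.740), replicate 3 high Atf3 (0.745) and replicate 4 a high complement median (0.688). Replicate 5 there had high Ccl3 (0.743), low Tgm1 (0.632), a high choroid plexus median (0.691), high Steap1 (0.668) and high Ttr (0.726). Replicate 6 there had low Plin2 (0.668), high Trf (0.661), low Fn1 (0.643), low Col4a1 (0.646), high Ccn1 (0.658) and low 2810032G03Rik (0.669). In labelled injured EPO, replicate 4 had high Epo (0.660).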

How the results depend on the processing

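The alternatives named here as added, the Eif2s3y covariate, the 2 arrays left out and the weighted group variances, were chosen after seeing the data. The planned Xist covariate was not run, since no row carries that symbol alone. Under the alternatives that keep the groups as labelled, no gene named as past the threshold changed direction, and the counts of EPO in sham, injury with EPO and the interaction stayed within 1.5 times of the reported count except where given here. Causes were not tested, except that fewer arrays enter under code 3D and that the thresholds act by construction. Signal over background was not measured, so what dim rows can show is unknown. Replicate numbers follow accession order. No paired analysis was possible because the numbers do not mark shared mice or litters.

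With only code 3D the counts were 437 for injury with EPO, 862 for EPO in sham, 56 for the interaction, 13 for injury averaged over EPO and 732 for EPO averaged over injury. With the code as a fixed block they were 902 for the interaction of injury and EPO and 945 for injury averaged over EPO, and array weights gave 3293 for the latter. Fitting only the groups compared gave 2019 for injury with EPO, and centring on the median gave 1 for injury without EPO. With at least 1.5-fold the counts were 1653 for injury with EPO, 2331 for EPO in sham, 300 for injury averaged over EPO and 831 for EPO averaged; with an adjusted p of 0.10 they were 2611 for the interaction and 2368 for injury averaged. Added alternatives moved no count by over 1.5 times. Leaving out each replicate gave 3819 to 5048 for EPO in sham, 2520 to 3791 for injury with EPO, 1233 to 2411 for the interaction, 1091 to 2511 for injury averaged, 3016 to 3665 for EPO averaged, 0 to 1 for injured EPO against sham none and 0 for the others. The reversal slope was 0.0122 within code 3D, 0.0281 without the 2 arrays in doubt and 0.0310 without injured EPO replicate 3, and ran from -0.189 to 0.0310 with each replicate left out. Of 188 named results, 91 lost their call within code 3D, 22 with the code as a block, 4 with centring and 3 with quantile normalization. The counts of list members past the threshold were followed for EPO in sham, injury with EPO and the interaction. Within code 3D 82 of these counts moved by over 1.5 times, or from 0, and 11 did not. With the code as a block 25 moved and 68 did not, and with 1 replicate left out 142 moved and 2090 did not.

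With the titles read the other way, which exchanges injured none and sham EPO, the counts were 4445 for injury without EPO, 0 for injury with EPO, 0 for EPO in sham, 3226 for EPO in injured, 3379 for injury averaged over EPO and 1557 for EPO averaged over injury, and the reversal slope was -0.642. By this construction 72 named results changed sign. For EPO in sham the log2 differences then were Tgm1 -0.12, Atf3 -0.11, Ccl4 -0.066, Ifit1 -0.17, Fos -0.052, Socs3 -0.16, Ccl2 -0.029, Csf2rb -0.061, Fn1 -0.078, Npas4 -0.10, Irf8 -0.092, S100a8 -0.056, Sox9 -0.0097, Slc4a4 0.053, Hsph1 0.051, Stard4 0.20, Lhx9 0.20, Tfrc 0.17, Neurod1 0.42, Cck 0.014, Cyp51 0.15, Hmgcs1 0.022, Sptb 0.040, Sqle 0.25, Camk2a 0.052, Nefl 0.22, Grik4 0.12, Itpka 0.066, Hpca 0.18, Npy2r 0.077, Ndst4 0.20, Pkp2 0.25, 9330120H11Rik 0.16, Thsd4 0.15, Ak4 0.21, Fibcd1 0.098, Itgbl1 0.081, Neurod6 0.29, P2ry12 0.25, Tmem119 0.39, Siglech 0.17, Selplg 0.21, Socs2 0.12, Slc40a1 0.16, Nr4a3 0.14. For injury with EPO they were Neurod6 -0.43, Itgbl1 -0.25, Fibcd1 -0.30, Ak4 -0.49, Npy2r -0.14, Ndst4 -0.39, Chrna5 -0.35, Orai2 -0.54, Gpr63 -0.42, Ccn1 0.78, Tgm1 1.39, Saa3 0.34, Timp1 1.36, Ccl11 0.34, Ccl9 1.45, Hmox1 0.81, H19 0.79, Ccl3 2.43, Lcn2 0.72. For injury averaged over EPO they were Neurod6 -1.37, Lcn2 3.38, Ccl11 2.02, for Ccl3, EPO averaged over injury, -1.87, with Lcn2 -2.27, Thsd4 0.73 there, for EPO in injured Aifm3 0.13 and for injury without EPO 2810032G03Rik -0.31.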

Other observations

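The test of the imprinted genes below was chosen after some of their values were seen.

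Camera called none of the following gene lists in the labelled sham EPO arrays. Of 18 immediate early genes, which follow neuronal activity, 8 rose and 3 fell (9 and 4 adjusted over the list alone), and camera gave no call (adjusted p = 0.112). Fos rose by 2.32 ± 0.21 (log2 difference ± SE, n = 6 per group) and Npas4 by 1.61 ± 0.35, while Homer1 (-1.01 ± 0.14) and Nr4a3 (-1.13 ± 0.14), named after their values were seen, fell. Hypoxia-inducible targets rose in 6 of 17 and fell in 2 (6 and 3 adjusted over the list alone), with Adm, the vasodilator adrenomedullin, at 1.93 ± 0.38. Camera gave no call (adjusted p = 0.540), and the median was -0.08 while the mean was 0.26. With each array centred on its median 5 of these targets rose and 6 fell. Myelin and oligodendrocyte genes rose in 3 of 17 (3 adjusted over the list alone; camera adjusted p = 0.0670), precursor genes in 2 of 9 (2; 0.0903; 1 rose and 2 fell when centred) and choroid plexus genes in 1 of 10 (1; 0.134), which was Steap1 (0.97 ± 0.17). Genes of neighbouring regions, thalamus or striatum, rose in 2 of 12 and fell in 1 (2 and 1; 0.0554), and neurogenesis genes rose in 1 of 14 and fell in 1 (0 and 1; 0.486; 5 fell when centred). Of 12 mitochondrial and ribosomal genes 1 rose, Rps3 (0.71 ± 0.16; 1 adjusted over the list alone), and camera gave no call (0.605). With each array centred on its median 1 of these 12 rose and 3 fell.

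The Y-linked gene Eif2s3y fell into 2 separate sets of arrays, 11 between 6.25 and 7.90 and 13 between 2.50 and 2.84. Values above 5 were found on 3 of 6 arrays in labelled sham none, 3 in sham EPO, 3 in injured none and 2 in injured EPO. Kdm5d, also Y-linked, was at least 4.78 on the 11 arrays and at most 3.06 on the 13. By both genes, 11 arrays read as those of male pups and 13 as those of female pups, with both sexes in every group.

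H19 was among the largest rises in the labelled sham EPO arrays, and a hypothesis was that its imprinted gene network rose together. Over the 17 other measured imprinted genes the median log2 difference was 0.34, of which 5 rose, such as Gatm (1.23) and Dlk1 (1.20), and 1 fell, Ppp1r9a (-0.40). Igf2, the neighbour of H19, was at 0.47 (adjusted p = 0.146). Camera gave a p of 0.0337 at its preset correlation and 0.286 with an estimated correlation. The median was 0.26 after another quantile normalization and 0.17 with each array centred on its median, with 4 genes up and 1 down in either case. A median above 0.5 was set to speak for a joint rise and one below 0.3 against it. The deposited values, at 0.34, lie between these bounds and both rescaled medians lie below the lower one, so a joint rise is not supported and stays undecided.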
